A study of Arabidopsis thaliana with 4 samples.

How the data were processed

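The samples were total RNA of whole seedlings of Arabidopsis thaliana, wild type or cerk1. Per the labels' protocols, seedlings grew for 8 to 10 days in MGRL medium with 0.1% agarose and 1% sucrose, with 16 h of light at 22 °C and 8 h of dark at 15 °C. They were moved to fresh medium in plates of 48 wells, left for 2 h, and kept with or without (GlcNAc)8 for 2 h more. The concentration of (GlcNAc)8 is given without its unit in the labels and is not printed here. The mutation in cerk1, the genetic background of either genotype and the number of seedlings per sample are not given in the sources used here.

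The 4 arrays were Agilent 44k arrays of 2 colours on 4 different slides, each with 39941 spots, of which 2256 were controls. Per the file headers, the spots were quantified with Agilent Feature Extraction 8.5.1.1, and the deposited files give a mean signal intensity and a local background intensity of each spot in each channel, with no normalization. Per the file headers, they also give processed signal intensities, from which the program had subtracted background and which it had dye-normalized by a linear step and LOWESS within each array. The deposited log10 ratio of each spot is that of red (Cy5) over green (Cy3) processed signals, and the deposited p-value of each spot is from the program's error model within 1 array. The value table deposited with the series held the scanner's log10 ratios, with a largest difference of 5e-10 and with no further scaling, centring or turning of the dyes. Its column medians were 0 and 0 in wild type and 9.87e-05 and 0 in cerk1. In it 3070 and 2602 spots of the wild-type arrays and 1883 and 1449 of the cerk1 arrays had a surrogate signal in a channel.

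Mean signals were corrected for local background with the normexp method of limma 3.58.1 (R 4.3.3) with an offset of 50. Each array was normalized by loess, with control spots at weight 0, and the log2 ratios were turned by the dyes in the labels into treated over untreated. Spots marked by the scanner as non-uniform or as population outliers were left out, 268 and 208 on the wild-type arrays and 453 and 351 on the cerk1 arrays. Saturated spots stayed in. Spots of 1 probe were averaged, and a gene took the probe with the highest mean signal over the 4 arrays. The 37478 probes included 26236 for genes, of 25665 loci, 8812 for intergenic sequence and 2430 for other transcripts, and 234 of the gene probes are listed by the array with several loci. Of 480 genes with more than 1 measured probe, 29 were called on any of them, 14 of these on some and not on all, and 0 in both directions. Gene symbols came from a table of the TAIR10.1 assembly, used for names alone, which held 25449 of the 25665 loci. Loci without a symbol there are printed by locus. Coordinates are those of the array design, and the genome build behind them is not given in the sources used here.

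Before dye turning, the log2 ratios of the arrays of a pair correlated across probes with r = -0.765 in wild type and 0.544 in cerk1. Exchanging the dyes turns a difference between the samples around and leaves dye bias as it is, so that a treatment effect gives a negative r and dye bias a positive one. The labels do not say whether the arrays of a pair hold the same RNA extracts. Each pair with exchanged dyes was therefore averaged and counted as 1 replicate, and no p-value entered the calls. A probe counted as measured in a genotype where it was well above background in at least 1 channel on both arrays. A gene was called where it was at least 2-fold the same way on each of both arrays. Genes past 2-fold in opposite directions were counted as a measure of dye bias. For a called gene not well above background in 1 channel on both arrays, the fold is a lower bound, the bright channel's mean against the higher of the gene's own signal and the lowest signal among probes well above background. Differences between genotypes were taken between arrays of the same dye orientation and called where they were at least 1 on the log2 scale in both orientations. Signals of single channels were normalized between arrays by the Aquantile method after loess. Untreated genotypes were compared within each dye, with a call at 2-fold in both, on genes well above background in at least 1 of the compared channels for each dye.

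The calls, the gene lists and the rule for naming genes were set before the data were examined. There were 20 lists with 453 entries. A list's median was ranked among those of 10000 random lists of the same size, matched in 10 bins of mean signal. The genes named are CERK1; in each genotype the 10 called genes with the largest and the 10 with the smallest mean ratio among those well above background in both channels of both arrays; up to 5 called genes with a bound; the 5 largest differences between genotypes in each direction; up to 4 called members of each list; and genes called the same way in both genotypes. The rule gave 78 genes, of which 77 were called in wild type, 57 higher and 20 lower. limma's lmFit and eBayes were also run on the dye-turned ratios of the 4 arrays with 1 coefficient per genotype, 2 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05, with the arrays taken as separate samples.

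The steps were tested on simulated data made from the real arrays. Among 22892 simulated wild-type genes, with 50 changed at each fold, the rule of 2-fold on both arrays called 0 genes of a true 1.5-fold change, 6 of a 2-fold, 50 of a 3-fold and 50 of a 4-fold change. It called 0 of 22692 unchanged genes in wild type and 0 of 23969 in cerk1, so that true changes near 2-fold are mostly missed. limma called 1, 42, 50 and 49 of the 50 wild-type genes at those folds. The changed genes were drawn only from those well above background in every channel, and the change was added after the offset. The shrinking of ratios of dim genes by the offset was therefore not simulated. The simulated noise was also scaled below that of a single array, so the shares found and the absence of false calls are best cases. Of 200 lists of unchanged genes 7.0% lay outside the central 95% of random lists.

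The alternatives were the scanner's processed signals, no background subtraction, median centring in place of loess, Aquantile scaling, other filters on dim probes, scanner marks ignored, the mean over a gene's probes, thresholds of 1.5-fold and 3-fold, the mean of the arrays at 2-fold, the scanner's p-value under 0.01 on both arrays, the series' value table, each array left out, and the dye orientation as a block in limma. Calculations outside R used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.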

Results

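Gene expression was measured in whole seedlings of Arabidopsis thaliana on 4 long-oligonucleotide arrays of 2 colours. Seedlings of the wild type or of the cerk1 mutant either received the chitin oligosaccharide (GlcNAc)8, a chain of 8 N-acetylglucosamine units, for 2 h or were left untreated. CERK1, chitin elicitor receptor kinase 1, is a receptor-like kinase with LysM domains at the cell surface. Each array held treated and untreated seedlings of 1 genotype, and each genotype had 2 arrays with the dyes exchanged. The treated sample was labelled with Cy5 on array 1 and with Cy3 on array 2 of each genotype. Such a pair of exchanged dyes was counted as 1 replicate, because the labels do not say whether its arrays hold the same RNA extracts, and the low number of arrays limits the precision of every value. Each array gave 37685 spots for plant sequences. Of these, 80.6% and 84.0% were well above background in the red channel on the wild-type arrays, against 88.7% and 90.9% on the cerk1 arrays. In the green channel the shares were 74.9% and 76.2% in wild type and 80.6% and 84.9% in cerk1.

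The mutated gene was examined first. CERK1 (AT3G21630) was lower in the mutant: in untreated seedlings its normalized log2 signal was 10.62 and 10.63 on the wild-type arrays and 6.96 and 7.69 on the cerk1 arrays. The mean difference between arrays of the same dye orientation was -3.30 ± 0.51 (SD over both orientations), or 9.86-fold, and it was 16.8-fold with the scanner's processed signals. CERK1 was also higher in chitin-treated wild type, with log2 ratios of treated over untreated of 1.79 and 1.66 on its arrays, though after median centring they were 2.64 and 0.63, short of 2-fold on array 2. In cerk1 the ratios were 0.24 and -0.25. The probe was well above background in every channel. It is placed at positions 7615586 to 7615645 of chromosome 3 by the array design, whose genome build is not given in the sources used here, and neither is the position of the probe relative to the mutation.

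**Figure D1:**
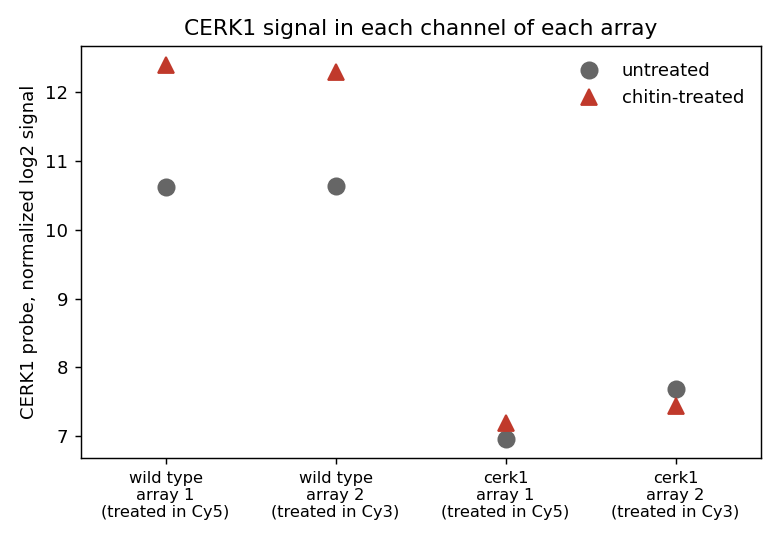
Normalized log2 signal of the CERK1 probe (vertical axis) on the 4 arrays (horizontal axis), with grey circles for untreated and red triangles for chitin-treated seedlings. Wild type lies at 10.62 and 10.63 untreated and 12.40 and 12.29 treated, while the 4 cerk1 channels lie between 6.96 and 7.69.

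The wild-type arrays address which genes answer the elicitor. After 2 h of chitin, genes of camalexin synthesis, early immune signalling, salicylate and phenylpropanoid synthesis, and detoxification were higher in wild type, and genes of flavonoid synthesis were lower. Of 22892 genes measured, 1161 were at least 2-fold higher on each array and 266 were at least 2-fold lower on each. 298 genes were at least 4-fold higher on both arrays and 15 at least 4-fold lower. The highest ratio in the main setting was that of AT1G26380, a FAD-binding protein of the berberine-bridge type, with log2 ratios of 4.79 and 4.80, or 27.7-fold. The lowest in the main setting was that of the vacuolar calcium exchanger CAX1, with log2 ratios of -2.94 and -2.69, or 7.04-fold lower.

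Beside AT1G26380, the genes with the highest ratios were led by DIR5, a dirigent protein, at 4.50 and 4.60, and AT2G18690, a protein of unknown function, at 4.47 and 4.49. The oxidase DIN11 followed at 4.06 and 4.68, and FRK1, a receptor-like kinase widely used as a marker of the response to microbial patterns, at 4.298 and 4.42. The cytochrome P450 CYP81F2, which acts in indole glucosinolate metabolism, was at 4.27 and 4.36, and the germin-like protein GLP9 at 4.19 and 4.33. The peroxidases AT5G39580 and AT3G03670 had ratios of 4.16 and 4.33, and of 4.04 and 4.11. PAD3, the cytochrome P450 of the last step of camalexin synthesis, was at 3.84 and 4.19.

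Every gene of the list for camalexin and other tryptophan-derived defence compounds was higher, 20 of 20, with a median log2 ratio of 2.48. Next to PAD3 and CYP81F2, the P450s CYP71A12 and CYP71A13 had ratios of 3.67 and 4.11, and of 3.40 and 3.47. Of 53 WRKY transcription factors measured, 21 were higher, none was lower and 32 were not called. WRKY53 was at 3.03 and 2.80, WRKY30 at 2.71 and 2.79, WRKY40 at 2.38 and 2.15 and WRKY33, a regulator of camalexin synthesis, at 2.22 and 2.23. Of 33 pattern receptors and genes of early immune signalling, 16 were higher and none was lower. PROPEP3, precursor of a danger peptide, had ratios of 3.39 and 3.61, YLS9 of 2.82 and 2.46, and the ubiquitin ligase PUB22 of 2.33 and 2.54. In the MAP kinase cascade 2 of 15 genes were higher, MPK11 at 1.34 and 1.12 and the MAP kinase kinase MEK1 at 1.31 and 1.44, with a list median of 0.82. After median centring both fell short of 2-fold on array 2, at 0.752 and 0.632, and so did MPK11 without background subtraction, at 0.906. On array 1 MPK11 was at 1.64 after median centring and at 1.081 without background subtraction.

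Genes of several hormone pathways were higher. Of 21 genes of salicylate synthesis and response, 10 were higher and none was lower. They included EDS16, the isochorismate synthase of salicylate synthesis, at 2.03 and 2.12, the pathogenesis-related glucanase BGL2 at 2.07 and 2.16, CBP60G at 1.99 and 2.00 and EDS5 at 1.65 and 1.82. Of 27 ethylene genes, 8 were higher, such as the transcription factor ERF5 at 2.00 and 2.16, the ethylene-forming enzyme EFE at 1.55 and 2.35, ERF-1 at 1.82 and 1.59 and AT5G51190 at 1.47 and 1.65. Of 29 jasmonate genes 4 were higher and 1 was lower, and 25 had a mean ratio above 0. JAZ1 was at 1.62 and 1.49, CYP94C1 at 1.43 and 1.62 and ACX1 at 1.27 and 1.32, while the storage protein gene VSP1 was lower at -1.48 and -1.56. JAZ1 (0.353 on array 2) and CYP94C1 (0.682) were among the named genes that lost the call after median centring. On array 1 their ratios rose instead, to 2.48 and 2.243. In that setting the mean ratios of named genes shifted by at most 0.354 from the main setting. Of 18 abscisate and dehydration genes only the dehydrin gene LTI30 was called, at 1.13 and 1.00, and of 28 auxin genes only IAA2, at 1.06 and 1.03. On array 2 both fell short of 2-fold without background subtraction, at 0.921 and 0.963, and after median centring, at 0.208 and 0.141.

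Secreted and wall-directed defences were higher as well. Of 17 chitinases and chitinase-like proteins, 8 were higher and none was lower, led by AT4G01700 at 3.09 and 3.81 and AT1G02360 at 3.36 and 3.25. AT2G43590 was at 2.87 and 3.09, and AT2G43620 at 2.40 and 3.46. In the list of secretion, callose and MLO genes 6 of 9 were higher. MLO12 had ratios of 2.78 and 2.66, MLO6 of 2.57 and 2.71, and the syntaxins SYP122 and SYP121 of 2.39 and 2.45, and of 1.71 and 2.08. Of 19 phenylpropanoid and lignin genes 11 were higher, among them the entry enzymes PAL1 at 2.28 and 2.25, PAL2 at 2.34 and 2.28, C4H at 2.36 and 2.097 and 4CL1 at 2.02 and 2.08. With the mean over its probes 4CL1 was only at 1.038 and 1.198. C4H (0.731 on array 2) and 4CL1 (0.789) were among the 22 named genes that lost the call after median centring. On array 1 their ratios rose instead, to 3.219 and 2.884. Of 24 glutathione S-transferases 12 were higher, led by GSTU12 at 3.54 and 3.72, GSTF7 at 3.13 and 3.19, GSTU11 at 2.89 and 3.27 and GSTU4 at 2.79 and 2.71. Of 26 stress, touch and calcium genes 10 were higher, including MYB15 at 2.81 and 2.84, the zinc finger gene STZ at 2.57 and 2.58, CML37 at 2.26 on both arrays and TCH3 at 2.13 and 2.32.

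Flavonoid synthesis went the other way: 4 of 12 genes were lower, none was higher, and the list median was -0.76. DFR was at -1.89 and -1.75, LDOX at -1.76 and -1.11, the MYB factor gene AT1G56650 at -1.37 and -1.10 and FLS1 at -1.15 and -1.03. AT1G56650 (-0.896 on array 2) was among the 7 named genes that lost the call without background subtraction. Of 23 expansins and xyloglucan endotransglucosylases, which loosen and remodel cell walls, 2 were lower, EXPA15 at -1.44 and -1.26 and XTH5 at -1.26 and -1.27. EXPA15 was among the named genes that lost the call after median centring, at -0.739 on array 1 and -2.092 on array 2. Of 15 root tissue markers 4 were lower, the aquaporin gene TIP2;3 at -2.19 and -2.09, the triterpene synthases MRN1 at -2.54 and -2.18 and THAS1 at -1.64 and -1.73, and the iron transporter IRT1 at -2.05 and -1.48. IRT1 lost its call with the mean over its probes. Beside CAX1 and MRN1, the lowest ratios were those of AT5G04120 at -2.71 and -2.47, the protease inhibitor gene DR4 at -2.43 and -2.61, AT1G14960 at -2.52 and -2.50, UMAMIT36 at -2.61 and -2.25, the aquaporin gene TIP2;2 at -2.52 and -2.21, AT4G12170 at -2.29 and -2.38, the auxin-conjugating enzyme gene GH3.17 at -2.54 and -2.12 and the xylosidase gene BXL1 at -2.39 and -2.25. Among 39 photosynthesis genes, markers of shoot tissue, LHB1B1 alone was called, at 1.44 and 1.35, and the list median was -0.01. After median centring LHB1B1 was at 2.297 and 0.08, and its call was lost. No gene was called among 12 circadian clock genes (median 0.12) and 9 reference genes (median 0.03). The medians of photosynthesis and reference genes changed sign in some of the alternative settings, in which they ranged from -0.26 to 0.03 and from -0.05 to 0.08.

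Medians were set against those of 10000 random lists of the same size, matched on mean signal, as a description of these arrays. In wild type 12 of the 20 lists lay above the central 95% of random lists and 3 lay below it, namely flavonoid synthesis, expansins and endotransglucosylases (median -0.41), and root markers (median -0.28). Root markers were outside in only 4 of 6 alternative settings: with the scanner's processed signals their median was -0.278 in a range from -0.316, and without array 1 it was -0.222 in a range from -0.264. The other 14 lists stayed outside in all 6. The 12 lists were camalexin synthesis, WRKY factors, MAP kinases (0.82), pattern receptors (1.05), ethylene (0.92), jasmonate (0.45), salicylate (1.02), chitinases (1.03), phenylpropanoids (1.498), secretion (1.88), glutathione S-transferases (1.22) and stress genes (0.91). The abscisate list (-0.12) and the auxin list (-0.09) lay inside, with the 3 lists of photosynthesis, clock and reference genes, though abscisate genes lay below the range in 2 of the 6 settings and auxin genes in 1. AT4G11040, a protein phosphatase gene whose untreated sample was not well above background on either array, was at least 2.04-fold higher, and was the only called gene of this kind in wild type. Its call was lost without background subtraction (0.825 and 0.643) and after median centring (0.945 on array 1).

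Both wild-type arrays gave much the same ratios: the median absolute difference between them was 0.15, and 2 genes passed 2-fold in opposite directions, a count that reflects dye bias. With the arrays taken as separate samples, limma called 8999 of 22583 genes at an adjusted p of 0.05, 4662 higher and 4337 lower, and such a p measures only the spread between arrays. The count was 5714 without array 1 of wild type, 316 after median centring in place of loess and 15431 with the dye orientation as a block. With the scanner's processed signals the calls were 1451 higher and 607 lower, so that 70.5% of calls were higher, against 81.4% in the main setting, and 197 genes passed 2-fold in opposite directions. After median centring 480 genes were higher and 79 lower, with 399 in opposite directions on the 2 arrays.

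The cerk1 arrays address whether the response needs CERK1. In cerk1 seedlings almost no gene passed 2-fold after the same treatment: of 23970 genes measured, 1 was at least 2-fold higher on each array, none was lower, and 5 passed 2-fold in opposite directions on the 2 arrays. On array 2 alone 8 genes were higher and 1 lower, and on array 1 alone 1 was higher and 10 lower. None of the 1412 genes called in wild type and measured in cerk1 was called there on both arrays. FRK1 had log2 ratios of -0.03 and -0.06, AT1G26380 of 0.10 and 0.30, PAD3 of -0.12 and 0.28, WRKY33 of -0.02 and -0.09, PAL1 of -0.04 and -0.13, and CAX1 of -0.27 and 0.12. The 1149 genes higher in wild type had a median cerk1 log2 ratio of -0.0019, with 95% of them between -0.25 and 0.23, against a median of 1.58 in wild type. The 263 genes lower in wild type had a median of -0.058, with 95% between -0.42 and 0.24, against -1.32 in wild type.

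The 1 gene called in cerk1 is annotated as AT7SL-1 (AT4G02970), a gene for the RNA of the signal recognition particle, while the array design describes the probe as a ubiquitin family protein. Its log2 ratios were 1.03 on both cerk1 arrays and 0.08 and 0.16 in wild type. They fell short of 2-fold without background subtraction, at 0.975 and 0.963, and on array 2 after median centring, at 1.403 and 0.643. Among the named genes called in wild type, the cerk1 means ran from -0.50 for TIP2;3 to 0.48 for AT2G43620, a chitinase gene with cerk1 ratios of 0.36 and 0.60. DIN11 was not well above background in any channel of the cerk1 arrays and was not measured there. No member of any of the 20 lists was called in cerk1, and list medians ran from -0.07 to 0.06. Medians of 4 lists were nonetheless outside the random range: camalexin synthesis at 0.06, jasmonate at 0.05 and photosynthesis at 0.05 lay above it, and root markers at -0.07 lay below it. None of the 4 stayed outside whichever array was left out. Without array 1 of cerk1 the medians of camalexin synthesis (0.008), jasmonate (0.027) and root markers (0.017) were inside the range, and so were those of camalexin synthesis (0.056), jasmonate (0.068) and photosynthesis (-0.004) without array 2. The 16 other lists lay inside, 10 of them with medians that changed sign in at least 1 alternative and 7 of them outside the range in at least 1, MAP kinases in 2 of 6 (0.077 without array 1).

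**Figure D2:**
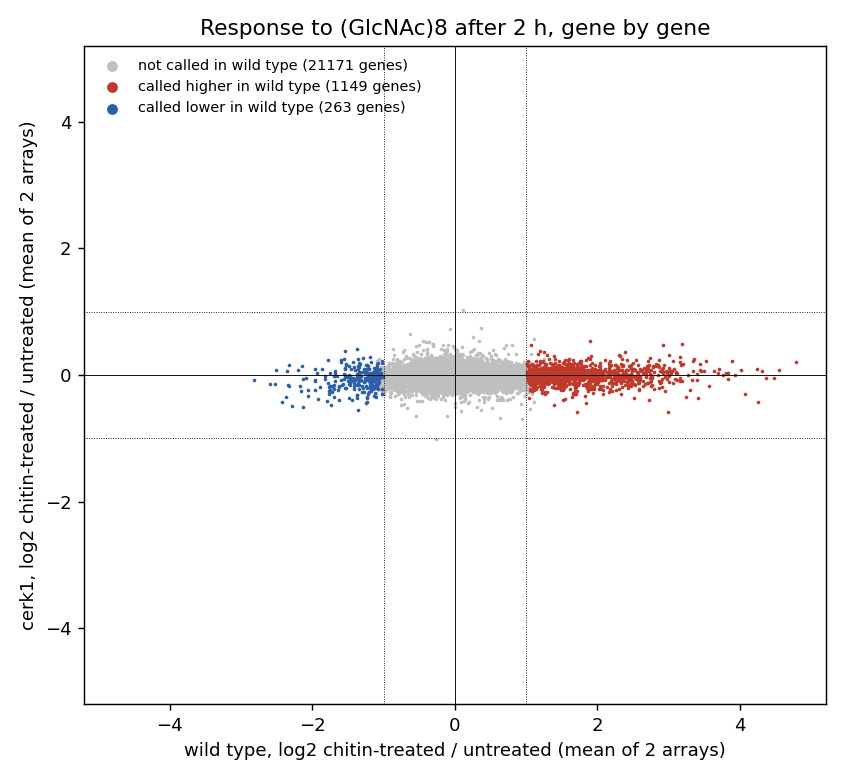
Mean log2 ratio of chitin-treated over untreated seedlings in wild type (horizontal axis) against that in cerk1 (vertical axis), with 1 point per gene measured in both genotypes and dotted lines at 2-fold. The 1149 genes higher in wild type (red) and the 263 lower (blue) spread along the horizontal axis and stay between -0.59 and 0.53 on the cerk1 axis.

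The standard deviation of the mean log2 ratio over genes was 0.09 in cerk1 against 0.57 in wild type. limma called 0 of 22583 genes in cerk1, and 726 had an unadjusted p under 0.05, fewer than the 1129 that chance gives. Dye bias shared by the genotypes stays in the spread of that fit and raises its p-values. The low count of 726 is thus no evidence against a response. limma also called 0 with the scanner's processed signals and after median centring, but 1149 genes, 500 higher and 649 lower, with the dye orientation as a block, in which the orientation takes up the dye bias shared by the genotypes. In that fit 4234 genes had an unadjusted p under 0.05.

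The difference of the responses was examined between arrays of the same dye orientation, so that dye bias cancels. Of 22583 genes measured on all 4 arrays, 1230 had a log2 response at least 1 higher in wild type than in cerk1 in both orientations, and 255 had one at least 1 lower. Of the 1230 genes, 1088 were also called higher in wild type, and of the 255 genes, 209 were also called lower. The largest differences in mean log2 response were those of GLP9 (4.68), AT1G26380 (4.59), AT2G18690 (4.53), DIR5 (4.48) and FRK1 (4.40). At the other end were CAX1 (-2.74), AT1G14960 (-2.59), BXL1 (-2.48), AT5G04120 (-2.45) and MRN1 (-2.43). The mean responses of the genotypes correlated with r = 0.03 across the 22583 genes and with r = 0.185 across the 1412 genes called in wild type, where the slope of cerk1 on wild type was 0.018. Genes are not independent replicates. limma's test of the difference called 5933 genes, 3369 with a larger and 2564 with a smaller response in wild type. With the dye orientation as a block it called 13400, 6670 larger and 6730 smaller, and with the scanner's processed signals 3189 larger and 3290 smaller, so that the excess of larger responses depends on the setting. The test called 3629 without array 1 of cerk1, 3714 without array 2 of cerk1, and 21 after median centring, with which 579 genes had a response at least 1 higher in wild type. With the scanner's processed signals 630 genes had a response at least 1 lower.

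**Figure D3:**
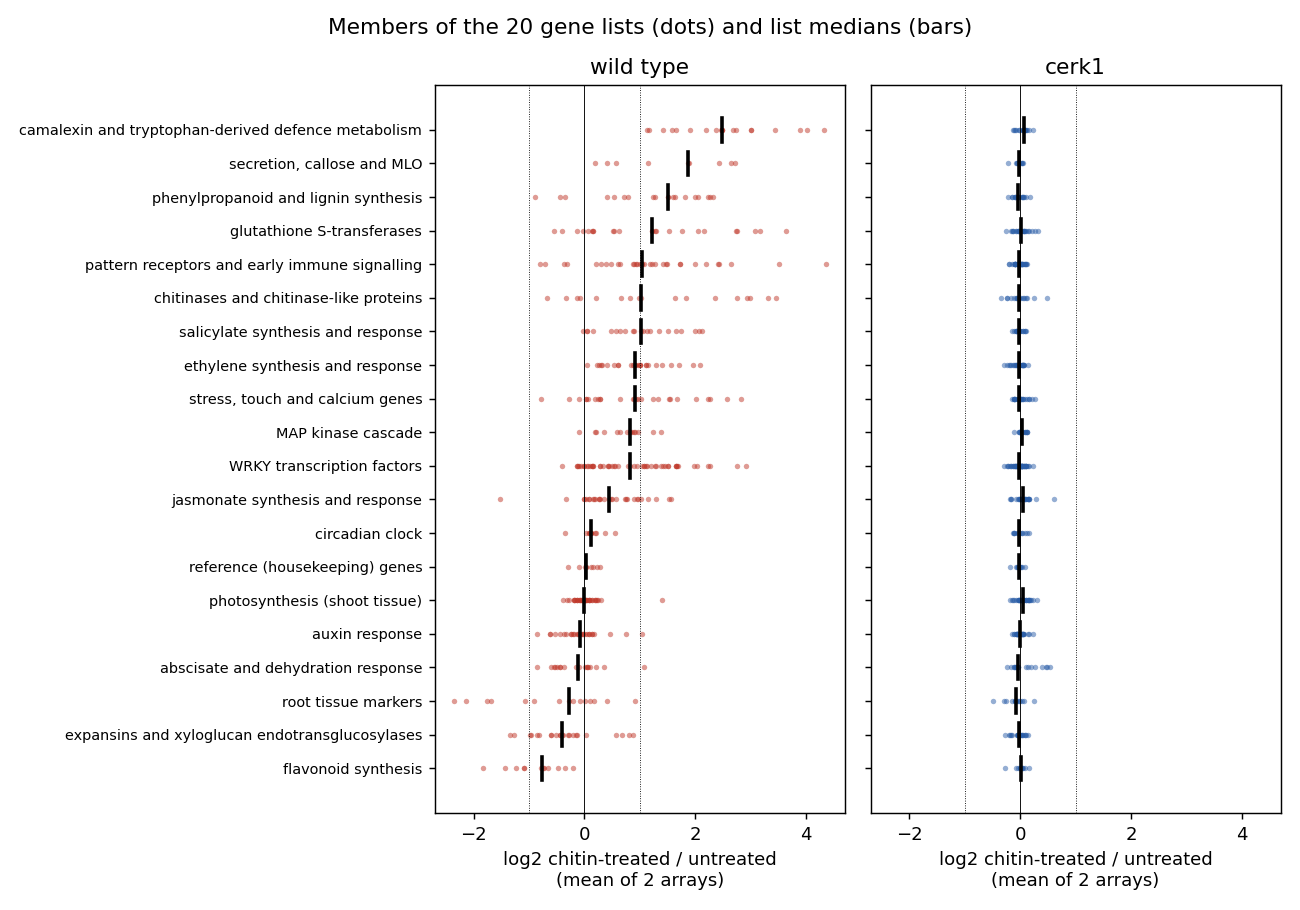
Mean log2 ratio of chitin-treated over untreated seedlings (horizontal axis) for each measured member (dots) of the 20 gene lists (vertical axis), in wild type (left) and cerk1 (right), with black bars at list medians and dotted lines at 2-fold. List medians run from -0.76 to 2.48 in wild type and from -0.07 to 0.06 in cerk1.

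Untreated seedlings of the genotypes were also set against each other, within each dye. Besides CERK1, several genes of the chitin response were lower in untreated cerk1 than in untreated wild type. The mean log2 difference was -2.29 for FRK1, -1.57 for AT1G26380, -1.53 for the chitinase gene AT2G43620, -1.499 for CYP94C1, -1.26 for GSTF7 and -1.03 for WRKY53. Of 22553 genes compared, 152 were at least 2-fold higher in cerk1 in both dyes and 254 at least 2-fold lower, and the differences in the 2 dyes correlated across genes with r = 0.871. CAX1 and DFR, which were lower with chitin in wild type, were higher in untreated cerk1 by 1.05 and 1.304, whereas DR4 (-2.08), AT1G14960 (-1.37) and THAS1 (-1.04) were lower in it.

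The largest differences of untreated seedlings, named here after their values were seen, lay mostly in genes not called after chitin. Among genes well above background in every untreated channel the lowest were AT4G13180, a short-chain dehydrogenase gene, at -4.78, AT4G20480 at -3.77 and AT5G52420 at -3.58. AT4G13200 was well above background in only 1 of the untreated cerk1 channels and was at least 35.1-fold lower in cerk1. HR4, a gene of the mildew resistance family RPW8, was not well above background in untreated wild type and was at least 69.5-fold higher in cerk1. The highest among genes above background throughout were AT4G07868 at 4.62, AT5G26290 at 3.81, the germin-like protein gene AT5G39180 at 3.44, the gene of the pyruvate dehydrogenase subunit E1 ALPHA at 3.385, and a further germin-like protein gene, AT5G39150, at 3.22. Both germin-like protein genes were higher with chitin in wild type. The genotypes lay on different arrays and came from different plants, so that array, plant batch and genotype cannot be told apart here. With the scanner's processed signals the counts were 324 higher and 592 lower, and after median centring 166 genes were lower.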

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

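The comparison of signal strength between arrays and the test for the same RNA in both channels were chosen after the lack of change in cerk1 was seen, and the test for hidden dye bias before it. The response to chitin differed between the genotypes. With arrays taken as separate samples, limma's test of the difference called 3369 genes with a larger and 2564 with a smaller log2 response in wild type, and the p behind these counts measures only the spread between arrays. The counts were 6670 and 6730 with the dye orientation as a block, 3189 and 3290 with the scanner's processed signals, and 21 and 0 after median centring, so neither their size nor the excess of larger responses holds in every setting. Of the 78 named genes 77 were in this test, and all 77 passed it, which adds no support, since their choice for large wild-type ratios or large differences on these arrays all but fixed that outcome. A further comparison was not tested: 26 named genes lay on opposite sides of 0 on all arrays of the genotypes, with cerk1 values no larger in size than that of GLP9, -0.42. The medians of 3 lists did so too, also untested: WRKY factors (0.82 in wild type, -0.01 in cerk1), ethylene genes (0.92 and -0.02) and phenylpropanoid genes (1.498 and -0.04).

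None of the genes called in wild type was called in cerk1, a pattern for which a requirement for CERK1 is the biological explanation that the design names. Dimmer arrays are argued against, since 98.95% of the genes called in wild type were measured on both cerk1 arrays. For hidden dye bias, the bias estimated from the wild-type arrays was taken off. After that, 0 of 1412 genes were at least 2-fold the same way on both cerk1 arrays. This count cannot decide the question, since the correction leaves each gene's mean over both arrays as it was. Those means lay between -0.59 and 0.53, so no gene could pass on both arrays. Bias equal on both arrays cancels in that mean, so bias of this kind hid no 2-fold mean response. The same RNA in both channels would leave no shared signal, yet over 20797 genes bright in every channel the cerk1 arrays correlated with r = 0.19 after that correction, against -0.24 before it. It stays open whether the elicitor reached the mutant seedlings as it did the wild type, and plants, genetic background and arrays differ with the genotype, so that the requirement for CERK1 is a hypothesis here.

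Some probes that the array design labels as intergenic or as other transcripts also differed between treated and untreated wild type. Whether they lie outside the genes of a newer annotation was not examined. Of 4726 intergenic probes measured in wild type, 14 were at least 2-fold higher on both arrays and 0 were lower, against 1 higher and 1 lower of 5978 in cerk1. The share called in wild type was 0.30%, against 6.23% of measured genes. The highest was at positions 9834132 to 9834191 of chromosome 4, in the array design's own build, with log2 ratios of 3.48 and 2.93. The next ones lay on chromosome 2 at 16503281 to 16503340, with 2.57 and 2.73, and on chromosome 3 at 7493265 to 7493324, with 2.43 and 2.87. Of 1955 probes for other transcripts measured in wild type, 18 were higher and 0 lower, against 0 called of 2120 in cerk1.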

How the results depend on the processing

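Of 174 values of counts and medians under alternatives, 112 stayed and 62 moved. A count stayed within 1.5 times of the main count, a median or named-gene ratio within the spread between arrays. Of 240 list medians 191 stayed and 49 moved, and of 546 named-gene values 421 stayed and 125 moved. None of the called values changed direction. Part of the named-gene outcome was fixed in advance. Aquantile scaling left all 78 values as they were. Leaving out 1 array gave 77 values for each wild-type array and 1 for each cerk1 array. It shifts a mean by less than that spread and cannot reverse a call made on both arrays. These values are therefore no evidence of stability. The largest shifts of a named gene's mean ratio were those of the dim AT4G11040, from 1.03 to 3.19 with the scanner's processed signals, and of 4CL1, from 2.05 to 1.12 with the mean over its probes. Of the 77 named genes called in wild type 22 lost the call after median centring, 7 without background subtraction, and 1, IRT1, with the mean over probes. Where values moved, the cause was not tested, except that other thresholds call more or fewer genes by construction. With the scanner's processed signals, and alike with the series' value table, 607 genes were lower in wild type, 6 were higher and 2 lower in cerk1, 630 had a response at least 1 lower in wild type, and genes lower in wild type had a cerk1 median of -0.051. These signals also gave a CERK1 difference of -4.07 and 324 higher and 592 lower genes in untreated cerk1, called again 1155 of the 1161 genes higher and all 266 lower in wild type, and had 197 genes in wild type and 211 in cerk1 past 2-fold in opposite directions, against 2 and 5 in the main setting. Without background subtraction 0 genes were higher in cerk1 and the median was -0.063. After median centring 399 and 391 genes were past 2-fold in opposite directions, while the mean ratios of named genes shifted by a median of 0.071 and at most 0.354. That setting called 480 genes higher (460 of the 1161) and 79 lower in wild type, 0 higher in cerk1, and 579 with a response at least 1 higher in wild type, with cerk1 medians of 0.023 for genes higher and -0.107 for genes lower in wild type, and 166 genes lower in untreated cerk1. At 1.5-fold 2235 genes were higher and 1085 lower in wild type, 3 and 1 in cerk1, and 2363 and 1126 differed between genotypes, with a median of -0.037. At 3-fold the counts were 509 and 47 in wild type, 0 higher in cerk1, and 519 and 40 for the difference, with a median of -0.138. With the mean of the arrays at 2-fold 1 gene was lower in cerk1 and the median was -0.055, as it was with the scanner's marks ignored. With the scanner's p-value 2279 genes were higher and 1628 lower in wild type and 6 and 6 in cerk1, with a median of -0.0245, and this rule gives no value for the difference between genotypes. Leaving out 1 array at a time gave 1 to 8 genes higher and 0 to 10 lower in cerk1, and medians from -0.054 to -0.050. For limma it gave 5714 to 8468 genes in wild type, 0 to 2 in cerk1 and 3629 to 4256 for the difference, with the lone array of a genotype assumed to vary like the others. limma called 316, 0 and 21 genes after median centring and 1633, 0 and 1651 with a demand for a 2-fold mean. With the dye orientation as a replicate block it called 15431 genes in wild type, 1149 in cerk1 and 13400 for the difference. Arrays of the same orientation deviated together (r = 0.817), but the orientation carries dye bias and does not pair samples. Each array had its own slide, so a block for slide was not possible. Signal over background limits dim genes most in the green channel, where the median spot was at 162 to 205 and negative controls were at 107.6 to 117.3.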

Other observations

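The gene families and the genes described in this part were picked after the results were seen, and so were all its tests except the one on genes missing from the genome. Families were defined by words in the array's gene descriptions, 22 in all, and compared with random gene sets matched on mean signal. Among receptor-like kinases, 21 of 64 kinases with a lectin domain were higher in chitin-treated wild type, none was lower, and the median log2 ratio was 0.43. Random sets held 2.89 such genes on average. LECRKA4.1 was at 2.77 and 2.76 on the wild-type arrays. Of 205 leucine-rich repeat kinases 30 were higher, against 10.0 in random sets, among them SOBIR1, a partner of receptor-like proteins, at 2.38 and 2.56 and IOS1 at 2.78 and 3.03. The median of that family was 0.02 and changed sign with the scanner's processed signals, without background subtraction and after median centring. Of 143 intracellular disease resistance genes of the NBS-LRR class 14 were higher, including ADR1-L1 at 1.64 and 1.72 and ZAR1 at 1.60 and 1.66. FAD-binding proteins of the berberine-bridge type had 13 of 33 genes higher and 1 lower, VQ motif proteins 9 of 30 higher and U-box proteins 9 of 47, with positive medians under each scaling. Class III peroxidases went both ways, with 15 of 67 higher and 4 lower, against 4.11 and 1.08 in random sets.

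Lower in wild type were arabinogalactan proteins, glycoproteins of the cell wall, with 11 of 41 genes lower, 1 higher and a median of -0.42, against 0.70 lower genes in random sets. AGP30 was at -1.77 and -1.80 and AGP4 at -1.38 and -1.44, while AGP5 was higher at 1.89 and 1.73. Aquaporins, as far as the words of the descriptions caught them, had 4 of 18 genes lower and a median of -0.55, with the plasma membrane aquaporin gene PIP2B at -1.95 and -1.51. The aquaporin genes TIP2;2 and TIP2;3, which were also called lower, are not among these 18. Cytosolic ribosomal proteins showed a small shift: none of 215 was called, 168 were below 0 on both arrays, and their median was -0.22, against a central 95% of random sets from -0.071 to 0.058, with medians of -0.24, -0.21 and -0.42 with the processed signals, without background subtraction and after median centring. In cerk1 the medians of these 3 families were -0.12, -0.04 and 0.01.

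Few genes passed small thresholds the same way on both cerk1 arrays, with dye bias left in. Such bias moves the dye-turned arrays apart, so these counts can miss small differences. With the dye orientation as a block limma called 1149 genes in cerk1, 500 higher and 649 lower. Of 22231 genes, 44 were higher and 64 lower by at least 0.3 on both arrays, and 6 and 7 by at least 0.5. The nitrate transporter gene NRT2.2 was at -0.99 and -1.03, just short of 2-fold on 1 array, against -0.14 and -0.38 in wild type. PHI-1 was at -0.82 and -0.57 in cerk1 and at 0.90 and 0.98 in wild type. The bifunctional nuclease gene ENDO2 was at 0.71 and 0.77, and the cold-regulated gene COR15A at 0.52 and 0.57.

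Genes of the chitin response were common among those lower in untreated cerk1. Of these 254 genes, 64 (25.2%) were called higher with chitin in wild type, against a mean of 13.4 and at most 28 in 10000 random sets, and 12 were called lower, against 2.80. The count of 64 was 117 of 591 (19.8%) with the scanner's processed signals and 39 of 166 (23.5%) after median centring. Of 145 genes higher in untreated cerk1 and measured in wild type, 14 were called higher with chitin, against a mean of 8.42 and up to 14 in the central 95% of random sets, and 9 were called lower, against 1.93 and up to 5. Both comparisons use the untreated wild-type channel, but a signal there that is too high by chance lowers the ratio of treated over untreated, so it works against the count of 64, though not against that of 12. A fault of 1 array is argued against by the differences in the 2 dyes, which come from separate arrays and correlated across genes with r = 0.871. As to loss of these genes from the mutant genome, 92.2% of the 64 were well above background in both untreated cerk1 channels. This cannot decide the question, since 80.6% and 90.9% of all plant spots passed that mark in those channels. The CERK1 probe passed it too, at a signal 9.86-fold lower than in wild type. The loss of CERK1, loss of other genes, genetic background, including regions carried along with the mutation, and growth and handling of the seedlings stay open.

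The 64 genes, beside those named in the account of untreated seedlings, include the co-receptor kinase gene SERK4 (-2.03), the chitinase gene EP3 (-1.59), the glucanase gene BG3 (-2.17) and the receptor kinase gene AT5G46330 (-1.35). They also hold AT3G21900 (-1.51), AT3G21920 (-1.35), AT3G21930 (-1.64), DMP1 (-1.26) and UGT71B6 (-1.22), which lie near CERK1 on chromosome 3. Of 172 genes within 100 loci of CERK1 on either side, 11 differed in untreated cerk1, against 1.8% of all genes compared. Over the genome, 31 pairs of differing genes within 3 loci of each other went the same way, against a mean of 10.0 and at most 20 in 1000 random sets. Those sets were matched on signal alone and did not keep neighbouring genes of a family together. The excess therefore cannot tell a shared region from related neighbours that act alike. AT3G21900, AT3G21920 and AT3G21930 share a domain in the array's descriptions and rose alike with chitin in wild type (2.512, 2.416 and 2.489).

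Root markers were lower with chitin in wild type, by the median of the list (-0.28), which lay just below the random range from -0.259 and inside it with the scanner's processed signals or without array 1. A smaller share of root RNA in the treated sample would lower them together, but 3 of the 15 were higher on both wild-type arrays, GLP5 (0.81 and 1.01), SCR (0.38 and 0.45) and EXPA7 (0.07 and 0.26), and 10 were lower on both. The members differed by an SD of 0.98, against a median difference of 0.18 between arrays for 1 gene. The value of EXPA7 on array 1 was smaller than that difference, so its place among the 3 is uncertain. A change in root share beside the genes' own regulation stays open.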
